A study of Pan troglodytes
Homo sapiens and Homo sapiens and Pongo pygmaeus
Homo sapiens with 16 samples.

How the data were processed

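RNA of human, chimpanzee, orangutan and rhesus macaque was hybridized to 16 two-colour arrays in 4 groups of 4. The deposited values are log2 ratios of the 2 dye channels, read as Cy5 over Cy3 from the order of the dyes in the titles. The image analysis, background correction and normalization used by the authors are not given in the sources used here. In the deposited table, 99.996% of values were the log2 of a ratio kept to 3 decimals, to within 0.01 of a whole thousandth. The array medians ranged from -0.60 to 0.04, so the table showed no sign of centring. It held 194 missing cells, and 76 cells at the highest value, 16.6, which equals a ratio of 100000, were treated as missing. Arrays of opposite dyes correlated at -0.67 to -0.51 in chimpanzee, -0.90 to -0.78 in orangutan and -0.87 to -0.85 in rhesus before turning. The dye swaps thus opposed each other, which a ratio of Cy3 over Cy5 would also give. The direction of the ratio itself therefore rests on the titles.

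The 4608 rows comprised 1056 probes for each species, 192 control rows and 96 rows each of 2 further kinds, D101 and D104, which entered no comparison. Same-numbered probes of different species were taken as 1 probe set: their values correlated at a median of 0.57 within an array, against 0.02 for the next number. Probes of a set are not independent, since the deviations of an array from the other self hybridizations correlated between the human and the other probes at a median of 0.25. Genes were named from the annotation of the human probe. It gave 1 symbol for 876 sets, several for 61 and none for 119, and 14 symbols were updated. Sets with several or no symbols are given by number.

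A set's value was the mean of the human probe and the probe of the compared species, or of all 4 probes for contrasts between species, the dye effect and the distance from human. Each array was then centred on its median over these values. Where the human probe or the probe of the compared species was used alone, the median of their mean was kept for centring. Centring was planned as an alternative to the deposited scale. It became the main setting only after the values were seen to be uncentred, and the uncentred values became the alternative. Limma version 3.58.1 in R version 4.3.3 was fitted to all 16 arrays with lmFit and eBayes, with a dye intercept and 1 coefficient per species, coded by the dye of the non-human RNA. Benjamini-Hochberg adjustment used a threshold of 0.05. Array summaries were compared with exact two-sided permutation tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

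The genes named were chosen from, for each species, the 10 highest and the 10 lowest past the threshold with the same sign on all 4 arrays. Added to these were the highest 2 and lowest 2 members of each gene list described, the highest 3 and lowest 3 sets past the threshold per contrast, and the 5 with the largest probe effect per species. The gene lists, 32 in all, were fixed before the data were examined, and 22 of them had at least 5 measured members. Camera, with a preset correlation of 0.01 and with an estimated one, and fry were run on these. The 8 lists described with examples were picked after their values were seen. In 10 of the 66 list tests the median, the mean and the direction of camera differed in sign. The fry test called 40 of 66 list tests for a net direction, and 64 for change in either direction.

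One chimpanzee array and 1 self hybridization have descriptions that name other dyes or species than their titles. Titles and channel sources were followed, with each array left out as an alternative. Replicate numbers follow accession order and pair no arrays. The alternatives were no centring, scaling to 1 spread, only sets measured on all 16 arrays, no dye term, other subsets of arrays, robust variance, array weights, the human probe, the other probe or all 4 probes, a fold minimum of 1, the reversed sign and each array left out. A trend on intensity and a median of duplicate spots were not run, because the values used here hold no intensities or duplicate spots. A dye term per set of arrays, centring on all probes, the probes of the species not compared, subsets by failed ratios, the distance on the pair of probes and gene lists without the arrays of conflicting labels were chosen after seeing the data. Signal over background was not analysed here.

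The fit was tested on simulated data with each array's own noise, over 5 runs with 200 changed sets. In chimpanzee, among 1056 sets, 60.3% of changes of 0.25 and 97.9% of changes of 0.5 were recovered, and 10.8% of calls were false. In orangutan the shares were 63.3%, 99.7% and 2.77%, and in rhesus, among 1055 sets, 48.7%, 100.0% and 0.241%. The 1 spread shared by all arrays therefore gave too many false calls in chimpanzee at the threshold of 0.05.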

Results

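RNA from chimpanzee, orangutan and rhesus macaque was compared with human RNA on 16 two-colour spotted arrays. Each species was hybridized against human RNA on 4 arrays, with its RNA on the Cy5 dye on 2 of them and on Cy3 on the other 2, and 4 further arrays carried human RNA in both channels. The array held 1056 probe sets, each with a human, a chimpanzee, an orangutan and a rhesus probe of the same number, so a transcript could be read on sequence of 4 species. Human probes carried a single gene name for 876 of the 1056 sets. The labels do not name the tissue. Nothing in the labels says that the arrays of a species came from separate animals or RNA extracts, so every p-value here measures only the spread between arrays, which may be technical. The number of arrays, 4 per comparison, limits the precision. Changes are log2 ratios of non-human over human RNA, averaged over the human probe and the probe of the compared species. Their direction rests on reading the deposited ratio as Cy5 over Cy3. Values on 1 probe alone keep the centring of this average. Unless given as SD, each ± is the standard error of the limma fit, which pools 1 residual spread over all 16 arrays. It therefore does not measure the spread of the 4 arrays of a species. The median SD between arrays was 0.256 in chimpanzee, 0.176 in orangutan and 0.141 in rhesus, while the median standard errors were 0.0945, 0.0941 and 0.0967.

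The first question was which transcripts differed between chimpanzee and human RNA. HSD17B6, a steroid dehydrogenase, was the lowest named gene in chimpanzee at -3.49 ± 0.09, an 11.3-fold difference. It was at -5.24 on the human probe and -1.75 on the chimpanzee probe, where CYP2A7 was lower at -2.96. CYP2A7, a cytochrome P450, fell by 3.25 ± 0.11, and LECT2, a secreted chemotactic protein, fell by 2.33 ± 0.09. ACADSB, a mitochondrial acyl-CoA dehydrogenase, was higher at 1.76 ± 0.08 (0.84 on the human probe alone), as were EPAS1, a hypoxia-inducible transcription factor, at 1.56 ± 0.15 and NNMT, a nicotinamide methyltransferase, at 1.53 ± 0.17. In all, 420 of 1056 probe sets passed an adjusted p of 0.05 by limma, 215 higher and 205 lower, and 38 of them changed by at least 1 on the log2 scale.

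Other high genes in chimpanzee were CTSC, the protease cathepsin C, at 1.44 ± 0.10, CD53, a tetraspanin of leukocytes, at 1.39 ± 0.09, and ALDH1A1, a retinaldehyde dehydrogenase, at 1.28 ± 0.13. MBL2, a lectin that starts a complement pathway, stood at 1.24 ± 0.12 (0.33 on the human probe alone) and EXT1, an enzyme of heparan sulfate synthesis, at 1.21 ± 0.12. Other low genes were FABP1, a fatty acid binding protein, at -2.15 ± 0.15, LGALS4, a galectin, at -2.05 ± 0.15 (-0.93 on the chimpanzee probe alone), and RGN, a calcium-binding protein also called regucalcin, at -1.53 ± 0.12. The same rule named 6 sets without a single gene name, of which set 43 was the highest at 1.83 ± 0.10 and set 145 the lowest at -3.32 ± 0.14. The largest adjusted p among these 20 sets was 1.40e-06 by limma. NNMT rested on 3 arrays near 1.86 to 2.12 and a value of 0.29 on chimpanzee array 4.

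In data simulated with the noise of these arrays and 200 of 1056 sets changed, 10.8% of the chimpanzee calls were false, above the nominal 5%. Such shares depend on how many sets change, so they need not hold for the real calls. The count fell to 232 with the 4 chimpanzee arrays alone in the fit. With array weights, where 3.93% of simulated calls were false, 377 sets passed, 342 of them among the 420. Without centring of the arrays, 69 of 318 sets were higher, 21.7% against 51.2%, and the median over all sets shifted by -0.17, so directions are relative to the array median. One chimpanzee array has a description that reverses the dyes of its title, and turning it by that description left 21 sets. Turned by their titles, all pairs of the 4 chimpanzee arrays correlated at 0.51 to 0.85, which argues against the description. Across all comparisons, 5 arrays had 39 to 70 failed ratios and the other 11 had 0 to 3. Most failures on these 5 arrays were in control rows, 37 to 61 per array. Only 2 to 12 per array were in the species rows that entered the comparisons. The 3 chimpanzee arrays with many failed ratios gave 366 sets, and the remaining 1 was too few for a fit.

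Orangutan RNA differed most from human RNA at TM4SF4, a membrane protein of the tetraspanin-like family, which was at -2.60 ± 0.10, a 6.08-fold difference. CYP2A7 was at -2.53 ± 0.13 and PCK1, the enzyme that commits carbon to glucose synthesis, at -2.06 ± 0.11. MAT1A, which makes S-adenosylmethionine, was at -1.95 ± 0.16 on probe set 158 and -1.17 ± 0.13 on set 128. CALM3, a calmodulin gene, stood highest at 1.90 ± 0.10, followed by MAOA, a monoamine oxidase, at 1.72 ± 0.13 and CYP2B6, a drug-metabolizing cytochrome P450, at 1.64 ± 0.10. In all, 657 of 1056 sets passed, 319 higher and 338 lower, and 63 of them changed by at least 1.

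Other high genes in orangutan were GRK5, a receptor kinase, at 1.38 ± 0.09 (0.68 on the human probe alone), EXT1 at 1.34 ± 0.14, CETP, which exchanges lipids between lipoproteins, at 1.22 ± 0.12, and PON2, a paraoxonase, at 1.19 ± 0.10. TOB1, an antiproliferative factor, stood at 1.18 ± 0.09, CRIM1, a membrane protein that binds growth factors, at 1.14 ± 0.08 and C1QB, a chain of complement C1q, at 1.11 ± 0.12 (0.71 on the human probe alone). Sets without a single gene name made up 6 of the 10 lowest, from set 145 at -2.36 ± 0.13 to set 373 at -1.65 ± 0.18. The largest adjusted p among the 20 sets was 8.55e-08 by limma. The CALM3 value came from 1 probe, with 3.85 on the orangutan probe and -0.06 on the human probe. CRIM1 was at -0.49 on the chimpanzee and rhesus probes, and CETP stood at 0.54 on orangutan array 4 against 1.40 to 1.53 on the others. With arrays scaled to the same spread, 415 sets passed. Without centring, 301 of 517 sets were higher, 58.2% against 48.6%, and centring on all probes of the 4 species gave 376 higher of 659, or 57.1%. The 2 orangutan arrays with many failed ratios gave 587 sets and the other 2 gave 559.

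Rhesus RNA was highest against human RNA at NFIL3, a basic leucine zipper transcription factor, which was at 2.58 ± 0.09. PON2 was at 2.0005 ± 0.11, SLCO1B1, an organic anion uptake transporter, at 1.93 ± 0.10 (1.23 on the human probe alone), SPARCL1, a matrix-associated protein, at 1.89 ± 0.09 and PCK1 at 1.74 ± 0.13. FABP1 was lowest at -2.75 ± 0.14, then RPS6KB2, a ribosomal protein S6 kinase, at -2.65 ± 0.12. In all, 639 of 1055 sets passed, 326 higher and 313 lower, and 71 of them changed by at least 1.

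MAT1A fell on both of its probe sets in rhesus, to -2.05 ± 0.15 on set 158 and -1.73 ± 0.15 on set 128. CA2, a carbonic anhydrase, was at -1.94 ± 0.09, ORM1, an acute phase plasma protein, at -1.86 ± 0.16 (-0.49 on the rhesus probe alone), LGALS4 at -1.83 ± 0.15, HAO1, a glycolate oxidase, at -1.76 ± 0.10 and RGN at -1.67 ± 0.11. Sets without a single gene name were again 6 of the 20, led by set 43 at 2.08 ± 0.10. The largest adjusted p among the 20 was 9.35e-08 by limma. Without centring, 389 of 516 sets were higher, 75.4% against 51.0%, with a shift of 0.19 in the median, and centring on all probes of the 4 species gave 494 higher of 675, or 73.2%. The ORM1 probe may also bind RNA of its close relative ORM2. All 4 rhesus arrays were among those with few failed ratios.

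**Figure D1:**
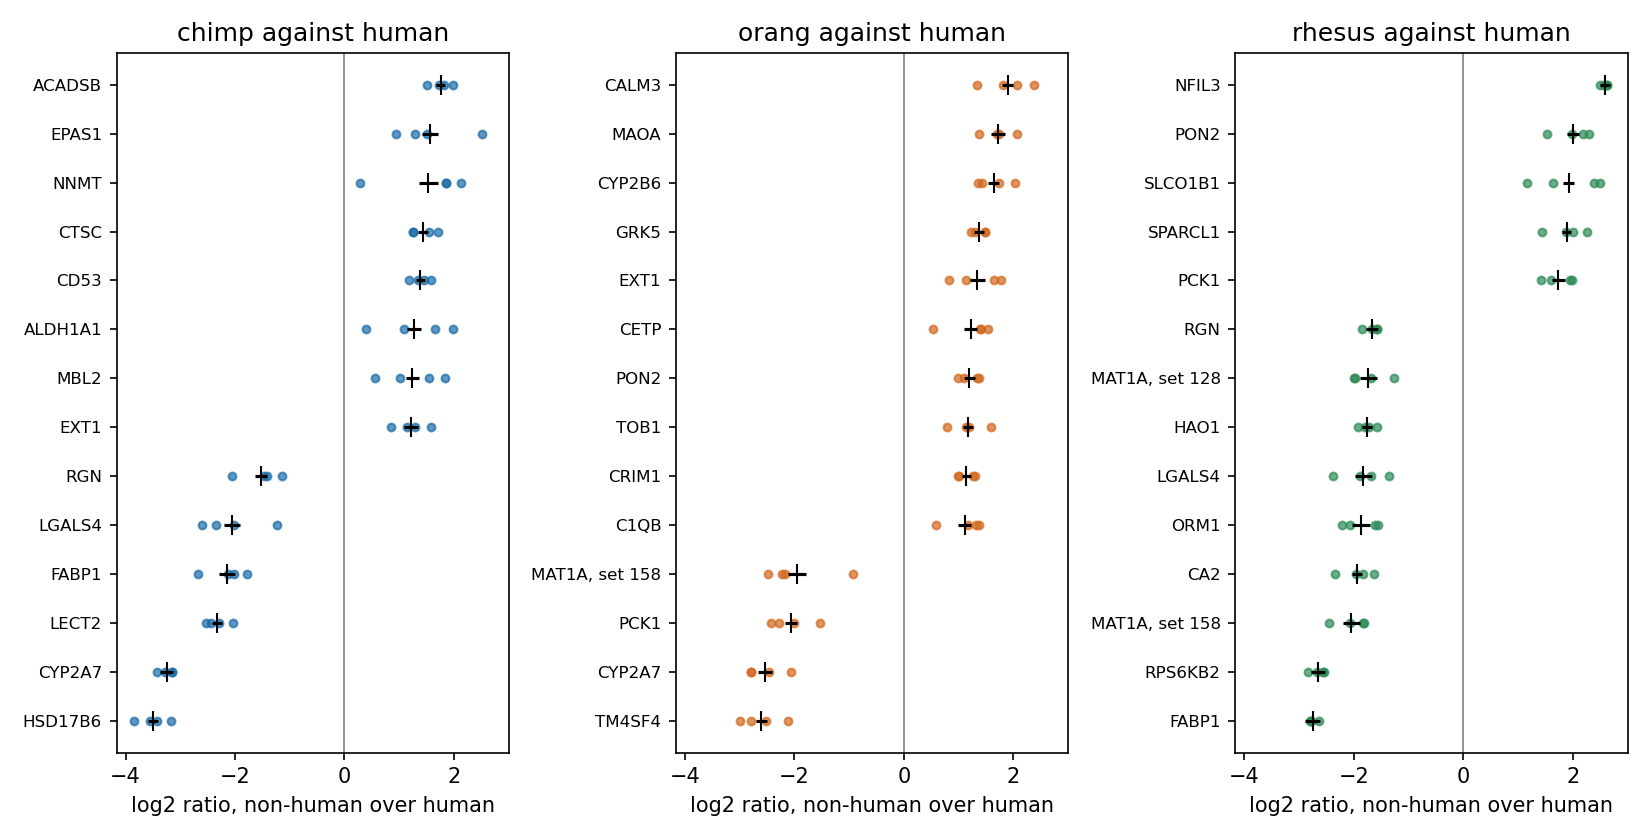
Log2 ratio of non-human over human RNA for the annotated genes named by the rule, 14 per species. Points are the 4 arrays turned to non-human over human, black marks the fitted value and horizontal bars its standard error. In chimpanzee, HSD17B6 lay at -3.49 and ACADSB at 1.76.

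Gene lists were fixed before the data were examined, and 8 of them are described here with their highest or lowest members. Enzymes of amino acid metabolism and the urea cycle fell in orangutan, where 13 of 17 members were lower and 2 higher. On the same arrays 6 of 8 leukocyte markers and 4 of 7 endothelial markers were higher, with 1 of each lower and camera adjusted p of 0.424 and 0.510. The share of cell types was not measured. The amino acid list was the single call among 66 list tests (camera with a preset correlation, adjusted p = 0.0419), and it was lost with an estimated correlation (adjusted p = 0.760 with camera), with the human probe alone (adjusted p = 0.744 with camera) and without orangutan array 1 (adjusted p = 0.0505 with camera). BHMT, which remethylates homocysteine, was at -1.21 ± 0.10 and MAT1A at -1.95 ± 0.16 on set 158 and -1.17 ± 0.13 on set 128, against OAT, ornithine aminotransferase, at 0.94 ± 0.12 and KYNU, kynureninase, at 0.18 ± 0.07, which did not pass without orangutan array 2 (0.17, adjusted p = 0.0783) or 3 (0.17, adjusted p = 0.0775). On the human probe alone OAT was at -0.73 and KYNU at -0.03. The 17 members split 4 higher and 6 lower in chimpanzee, with BHMT at 0.96 ± 0.10 and KMO, kynurenine monooxygenase, at 0.74 ± 0.08 (0.41 on the human probe alone), and 7 higher and 9 lower in rhesus, with ASL, argininosuccinate lyase, at 0.93 ± 0.11. Adjusted over the list alone, the counts were the same in each species.

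Of 13 fatty acid metabolism genes, 9 were lower and 2 higher in orangutan, 4 lower and 3 higher in chimpanzee and 6 lower and 6 higher in rhesus. ACSL1, an acyl-CoA synthetase, was at -1.34 ± 0.10 in chimpanzee and -1.005 ± 0.10 in orangutan. AGPAT2, an enzyme of phospholipid synthesis, was at -1.01 ± 0.17 in orangutan and -1.33 ± 0.18 in rhesus, with -0.48 and -0.64 on the own-species probes alone. HSD17B4 was at 0.94 ± 0.10 in chimpanzee and HADHB, a subunit of the trifunctional protein of beta oxidation, at 0.78 ± 0.10 in rhesus. In chimpanzee, 4 were higher and 4 lower adjusted over the list alone, and the other counts were the same. This list and the other 6 described here did not pass the camera test in any species (smallest adjusted p = 0.424).

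Of 25 genes of cytochrome P450 and drug metabolism, 8 were higher and 5 lower in chimpanzee, 7 higher and 9 lower in orangutan and 6 higher and 12 lower in rhesus. FMO5, a flavin monooxygenase, was at -1.52 ± 0.10 in orangutan, and CYP2B6 and CYP1A1 were at -1.31 ± 0.09 and -0.82 ± 0.11 in rhesus. The counts adjusted over the list alone differed for 2 of these: 9 were higher in chimpanzee and 14 lower in rhesus. The orangutan members had a median of 0.03 and a mean of -0.03. GSTZ1, a glutathione transferase, was at -0.92 ± 0.09 in chimpanzee. CYP2A7 has close relatives whose RNA may bind to the same probe. Among 9 apolipoprotein and lipoprotein genes, 5 were lower and 1 higher in chimpanzee, 3 and 3 in orangutan, and 2 and 6 in rhesus. APOA1, the main protein of high density lipoprotein, was at -0.73 ± 0.16 in chimpanzee, -1.003 ± 0.18 in orangutan and -0.33 ± 0.12 in rhesus. Without chimpanzee array 4 it was at -0.38 in chimpanzee, and the rhesus value did not pass without rhesus array 2 (-0.27), 3 (-0.29) or 4 (-0.32). In chimpanzee, 6 were lower adjusted over the list alone. On the rhesus probe alone APOA1 was at 0.28. LCAT, which esterifies cholesterol in plasma, was at -0.78 ± 0.11 in chimpanzee.

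Of 13 plasma and acute phase protein genes, 6 were lower and 1 higher in chimpanzee, 2 lower and 6 higher in orangutan and 3 lower and 5 higher in rhesus. There were 2 higher in chimpanzee and 7 in orangutan adjusted over the list alone. FGG, a fibrinogen chain, was at 0.52 ± 0.14 in chimpanzee and 1.07 ± 0.13 in orangutan, with 0.22 on the human probe alone in each, while AFM, a plasma vitamin E binding protein, was at -1.10 ± 0.09 and -1.31 ± 0.10. The FGG value in chimpanzee did not pass without array 4 (0.28, adjusted p = 0.0774), and 1 of its 4 arrays was negative, at -0.91. IGF1, a growth factor, was at -0.41 ± 0.11 in orangutan (-0.22 on the orangutan probe alone) and 0.92 ± 0.10 in rhesus (0.56 on the human probe alone). Of 11 complement genes, 5 were higher and 2 lower in chimpanzee, 2 and 5 in orangutan and 5 and 4 in rhesus. MBL2 was at 1.51 ± 0.12 and its protease MASP2 at 1.03 ± 0.08 in rhesus, but on the human probe they were at 0.07 and 0.49 and on the rhesus probe at 2.95 and 1.58. C4BPA, a complement inhibitor, was at -0.68 ± 0.13 in chimpanzee (-0.36 on the chimpanzee probe alone), -0.86 ± 0.12 in orangutan (-0.23 on the orangutan probe alone) and -0.53 ± 0.11 in rhesus, where the rhesus probe alone gave 0.32. Of the 4 chimpanzee arrays, 1 was positive for C4BPA, at 0.23, and without array 4 it was at -0.52. Adjusted over the list alone, the complement counts were the same.

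Of 8 leukocyte markers, 6 were higher and 1 lower in orangutan, 3 higher and none lower in chimpanzee, and 1 higher and 1 lower in rhesus. In orangutan, 7 were higher adjusted over the list alone. CD4 was at 0.69 ± 0.09 and ITGB2, an integrin of leukocytes, at 0.68 ± 0.10 in orangutan, with 0.32 and 0.09 on the human probe and 1.06 and 1.27 on the orangutan probe. PTPRC, the common leukocyte antigen CD45, was at -0.26 ± 0.09 in orangutan, and at 0.63 on the orangutan probe alone. It did not pass without orangutan array 2 (-0.19, adjusted p = 0.150). CD53 was at -0.53 ± 0.08 in rhesus (-0.10 on the rhesus probe alone) against 1.39 in chimpanzee. Of 8 matrix and stromal genes, 4 were lower and none higher in chimpanzee and in rhesus, and 2 were higher and 3 lower in orangutan. FN1, fibronectin, was at -1.15 ± 0.13 in chimpanzee and BGN, biglycan, at -0.65 ± 0.08 in rhesus, with 0.10 on the rhesus probe alone. Adjusted over the list alone, the matrix counts were the same.

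The species were also set against each other through their ratios to human RNA, on the mean of the 4 probes. HSD17B6 was higher in rhesus than in chimpanzee by 4.05 ± 0.13 and in orangutan than in chimpanzee by 2.56 ± 0.13. LECT2 was higher in orangutan than in chimpanzee by 2.61 ± 0.13, while FMO5 was at -2.24 ± 0.13 and BHMT at -2.16 ± 0.13 in that contrast. CYP2A7 was higher in rhesus than in chimpanzee by 3.65 ± 0.17. EPAS1 was at -2.77 ± 0.16 and CA2 at -2.23 ± 0.12 in rhesus against chimpanzee. PCK1 was higher in rhesus than in orangutan by 3.80 ± 0.16 and TM4SF4 by 3.44 ± 0.17, while CYP2B6 was at -2.91 ± 0.13. By limma, 466 of 1055 sets differed between orangutan and chimpanzee, 482 of 1054 between rhesus and chimpanzee and 534 of 1054 between rhesus and orangutan. Arrays scaled to the same spread gave 250, 286 and 308 sets. Without centring, 268 of 355 sets were higher in orangutan than in chimpanzee, 75.5% against 49.1%, and 269 of 347 in rhesus than in chimpanzee, 77.5% against 49.2%.

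A further question was how the ratio depended on the species of the probe. Without intensities, a gain of signal from non-human RNA cannot be told from a loss of human signal. The ratio of non-human over human RNA was higher on the own-species probe than on the human probe by 0.43 ± 0.15 (SD, n = 4) in chimpanzee, 0.68 ± 0.13 in orangutan and 1.01 ± 0.07 in rhesus. All 12 arrays were positive, although the exact sign permutation test with 4 arrays cannot go below 0.125, the two-sided p found for each species. The human self hybridizations ranged from -0.07 to 0.15 for the same differences. By limma, 712, 879 and 981 sets differed between the probes, of which 704, 867 and 973 were higher on the own-species probe. The largest probe differences in chimpanzee were 3.48 ± 0.19 at HSD17B6, 2.24 ± 0.16 at LGALS4, 1.94 ± 0.37 at ELMO1, 1.89 ± 0.14 at set 1005 and 1.82 ± 0.10 at ACADSB. In orangutan they were 3.91 ± 0.22 at CALM3, 3.83 ± 0.17 at SAFB, 3.39 ± 0.27 at set 579, 3.34 ± 0.13 at OAT and 2.89 ± 0.16 at EIF4A3. In rhesus they were 4.47 ± 0.11 at OAT, 3.37 ± 0.18 at IL6R, 3.25 ± 0.19 at GMFG, 3.25 ± 0.27 at RUVBL2 and 3.19 ± 0.16 at FGB.

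The probe effect was larger in rhesus than in chimpanzee by 0.58 and than in orangutan by 0.33, each with an adjusted p of 0.0429 in a two-sided exact permutation test. Orangutan exceeded chimpanzee by 0.25 (exact permutation p = 0.0571). Among arrays with many failed ratios the mean effect was 0.50 in chimpanzee (n = 3) and 0.74 in orangutan (n = 2), and among the others it was 0.23 (n = 1) and 0.62 (n = 2). On the probes of species not hybridized the mean difference from the human probe ranged from 0.17 to 0.28 over 4 arrays, and single arrays from 0.038 to 0.39. Single probes were centred on the array median of the mean of the 2 probes, so part of the probe effect stayed in their values as an offset. The median over sets on the human probe was -0.23 in chimpanzee, -0.40 in orangutan and -0.53 in rhesus. On the own-species probe it was 0.26, 0.39 and 0.53. The lean of the following counts restates this offset in part. With the human probe alone, 465 of 563 called sets were lower in chimpanzee, 629 of 750 in orangutan and 755 of 832 in rhesus. With the own-species probe alone, 511 of 611, 633 of 783 and 722 of 799 were higher. In rhesus, 456 sets passed on both single probes with opposite signs, each lower on the human probe and higher on the rhesus probe.

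**Figure D2:**
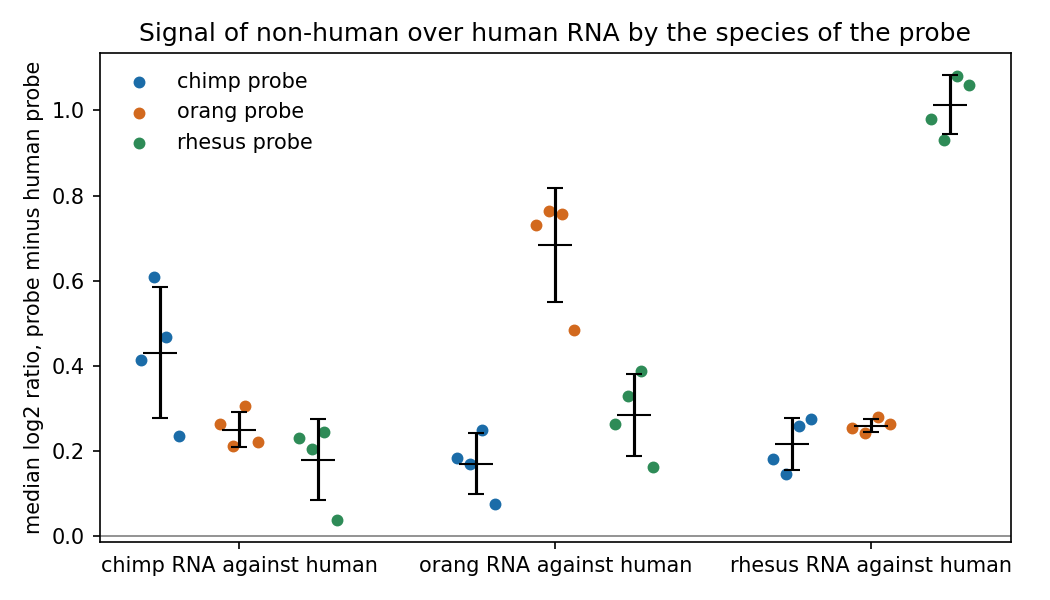
Median log2 ratio of non-human over human RNA on each non-human probe minus that on the human probe, by the RNA hybridized. Points are the 4 arrays, black marks the mean and bars the SD. The own-species probe gave 0.43, 0.68 and 1.01.

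Distance from human was summarized per array as the median absolute log2 ratio over probe sets. This measure also holds the noise of each array and the dye effect, and the spread between arrays was largest in chimpanzee. In the limma fit on the human and own-species probes, the median absolute difference was 0.186 in chimpanzee, 0.305 in orangutan and 0.296 in rhesus. The distance per array was 0.115 ± 0.050 (SD, n = 4) in human against human, 0.235 ± 0.028 in chimpanzee, 0.289 ± 0.059 in orangutan and 0.276 ± 0.022 in rhesus. No pair of groups passed after adjustment over 6 comparisons. Each species against the self hybridizations gave a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give, and an adjusted p of 0.0571. The p was 0.0857 for chimpanzee against rhesus (adjusted p = 0.129), 0.171 for chimpanzee against orangutan (adjusted p = 0.206) and 0.714 for orangutan against rhesus (adjusted p = 0.714). Among arrays with many failed ratios the mean was 0.224 in chimpanzee and 0.316 in orangutan. Among the others it was 0.115 in human, 0.268 in chimpanzee (n = 1), 0.263 in orangutan and 0.276 in rhesus. By limma, 162 sets differed between the dyes, 105 higher on Cy5, with 0 of them at 1 or more. In the self hybridizations alone 73 sets did so, 60 higher on Cy5, with 2 of them at 1 or more. Without centring, 10 of 1028 were higher on Cy5, 0.973% against 64.8%.

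**Figure D3:**
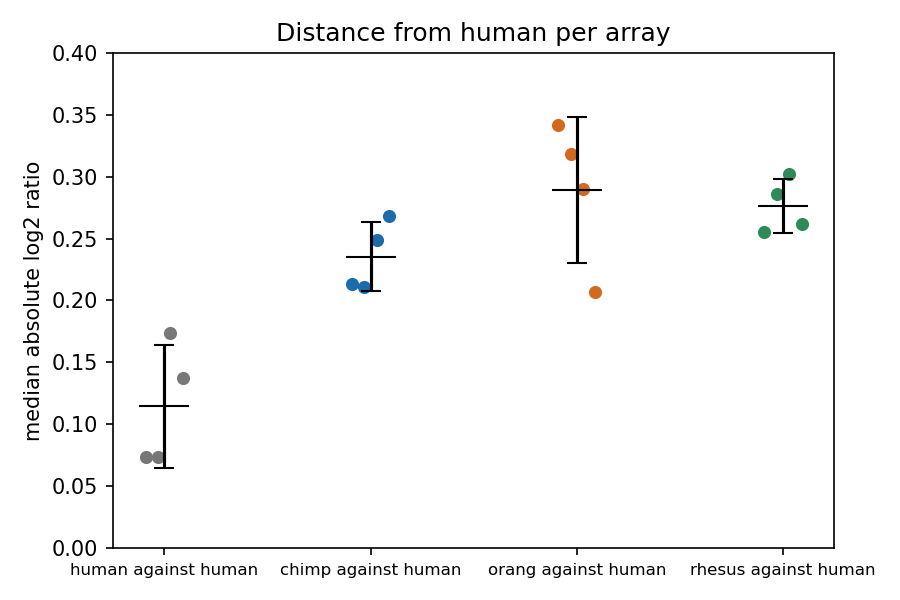
Median absolute log2 ratio per array over probe sets, by the RNA set against human RNA. Points are the 4 arrays, black marks the mean and bars the SD. The self hybridizations averaged 0.115 and the orangutan arrays 0.289.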

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

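The tests of the probe effect and of the chimpanzee count, and the sign patterns for the species counts, were chosen after those results were seen. The sign patterns for the probe effect and the gene lists and the splits between species were set before.

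The ratio of non-human over human RNA was higher on the own-species probe than on the human probe, by 0.58 more in rhesus than in chimpanzee and by 0.33 more in rhesus than in orangutan, each a tested difference between species. The tables argue against an imbalance of dyes or arrays, since the effect was positive on 12 of 12 arrays over both dye orientations. Sequence mismatch between RNA and probe stays open, since the difference of 0.58 that raised it cannot also test it. Probe sequences were not analysed here, so mismatches were not counted. With 8 sign patterns per species, too few for a share under 0.05, 1 pattern, the real one, gave as many sets: 712 in chimpanzee against at most 130 in the others, 879 in orangutan against 311 and 981 in rhesus against 0.

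Fewer sets passed in chimpanzee, 420, than in orangutan, 657, or rhesus, 639. Arrays with many failed ratios are argued against as the whole cause, because among them orangutan passed 221 more sets than chimpanzee from fewer arrays. The median SD between arrays was 0.256 in chimpanzee, 0.176 in orangutan and 0.141 in rhesus. The fit shares 1 residual spread over all 16 arrays, with median standard errors of 0.0945, 0.0941 and 0.0967, so the spread of 1 species does not lower its count alone. In simulations with each array's own noise, 60.3% of changes of 0.25 were recovered in chimpanzee, 63.3% in orangutan and 48.7% in rhesus. These values argue against a larger spread between the chimpanzee arrays as the cause of the lower count of 420. With only the arrays of each comparison in the fit, 232 sets passed in chimpanzee, 638 in orangutan and 759 in rhesus. For these counts a larger spread stays open. The SD of differences shared by arrays of opposite dyes was in chimpanzee 0.787 of that in the lower of the other species, up to 0.418 over array pairs in chimpanzee and from 0.460 in orangutan. The bound of this test was loosened after its value was known, so no conclusion is drawn from it. A smaller distance between chimpanzee and human also stays open. The median absolute fitted difference over sets was 0.186 in chimpanzee, 0.305 in orangutan and 0.296 in rhesus. A smaller distance was not tested apart from compressed ratios on the chimpanzee arrays. With 8 sign patterns, again too few for a share under 0.05, 1 pattern gave as many sets, the highest of the others being 112 in chimpanzee, 0 in orangutan and 0 in rhesus.

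The contrasts between species differed at 466 sets for orangutan against chimpanzee, 482 for rhesus against chimpanzee and 534 for rhesus against orangutan. In each, 1 of the 35 splits of the 8 arrays gave as many sets, the real one, with at most 139, 65 and 1 sets in the others. This is the smallest share that 35 splits can give. The splits reassign arrays that may be technical, so they cannot exclude chance differences between animals or RNA samples. Many failed ratios marked 3 chimpanzee arrays and 0 rhesus arrays, so that contrast also followed this technical difference. Between orangutan and chimpanzee, LECT2 differed by 2.61, HSD17B6 by 2.56, CYP2B6 by 1.95, FMO5 by -2.24, TM4SF4 by -2.18 and BHMT by -2.16. Between rhesus and chimpanzee, HSD17B6 differed by 4.05, set 145 by 3.80, CYP2A7 by 3.65, RPS6KB2 by -2.77, EPAS1 by -2.77 and CA2 by -2.23. Between rhesus and orangutan, PCK1 differed by 3.80, TM4SF4 by 3.44, CYP2A7 by 3.02, CYP2B6 by -2.91, ORM1 by -2.61 and MAGED1 by -2.46.

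In 6 of 144 groups of 4 arrays, 1 array stood apart from the others relative to their range. Chance gives about 1 in 20 groups, so these are no excess, and some of the gaps were small. The own-probe effect was 0.48 on orangutan array 4 and 0.73 to 0.76 on the others. NNMT was at 0.29 on chimpanzee array 4 against 1.86 to 2.12, and CETP at 0.54 on orangutan array 4 against 1.40 to 1.53. On rhesus array 3, set 118 was at 1.82 against 1.58 to 1.61, FABP1 at -2.63 against -2.80 to -2.78 and MAOA at 1.502 against 1.27 to 1.30.

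Rows that entered no comparison lay outside the range of the self hybridizations on some arrays, as medians minus the array median of Cy5 over Cy3. Control rows were at 0.71 on orangutan array 4, -0.04 and -0.26 on orangutan arrays 1 and 2, -0.04, 0.00 and -0.38 on chimpanzee arrays 1, 2 and 4 and 0.17 on rhesus array 1, against 0.18 to 0.61 in the self hybridizations. The D101 rows were at -0.12, -0.24 and -2.30 on chimpanzee arrays 1, 3 and 4, -0.74 and -0.79 on orangutan arrays 1 and 2 and 0.63 and -0.21 on rhesus arrays 1 and 3, against -0.10 to 0.62. The D104 rows were at 0.71 on chimpanzee array 2, -2.10 on chimpanzee array 4 and -0.44 and -0.72 on orangutan arrays 1 and 2, against -0.11 to 0.69.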

How the results depend on the processing

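Of the named-gene values under alternatives, 2823 kept their direction and side of the threshold, 90 no longer passed, 28 newly passed and 48 changed sign. Choice of probe and of centring limited the directions, and signal over background was not analysed here. Unless a cause is given, the cause was not tested. No paired analysis was possible because replicate numbers follow accession order only.

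A fold minimum of 1 left 38 sets in chimpanzee, 63 in orangutan and 71 in rhesus by construction. The chimpanzee arrays alone gave 232 sets, and turning 1 array by its description 21. Scaling to the same spread gave 415 sets in orangutan, 250 for orangutan against chimpanzee, 286 for rhesus against chimpanzee and 308 for rhesus against orangutan. Without centring, 313 sets differed between rhesus and orangutan and 1028 between the dyes, against 162 with centring. With centring, the self hybridizations alone gave 73 between the dyes. The median absolute log2 ratio without centring was 0.411 in human, 0.510 in chimpanzee, 0.398 in orangutan and 0.429 in rhesus. Scaling set it to 0.210 in every group by construction, and the mean of the human and own-species probes gave 0.266 in chimpanzee and 0.312 in rhesus. No gene list passed (0 calls) with an estimated correlation (adjusted p = 0.760 with camera), with the human probe alone (0.744) or without orangutan array 1 (0.0505).

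On the human probe alone, chimpanzee FGB was at -0.015, PON1 at -0.088, CSF1R at -0.069, HSPG2 at -0.065 and COL6A1 at -0.25. Orangutan CALM3 was at -0.056, OAT at -0.73, KYNU at -0.032 and LYN at -0.28, and rhesus MAOA at -0.037, OAT at -0.84, CD36 at -0.059, LYN at -0.48, CD4 at -0.58, HSPG2 at -0.050 and NID1 at -0.38. On the own-species probe alone, PTPRC was at 0.41 in chimpanzee and 0.63 in orangutan, and rhesus HPR was at 0.89, C1R at 0.13, C4BPA at 0.32, APOA1 at 0.28, FBLN5 at 0.62 and BGN at 0.099. The centring left an offset in single-probe values. Its median over sets was -0.23 in chimpanzee, -0.40 in orangutan and -0.53 in rhesus on the human probe. On the own-species probe it was 0.26, 0.39 and 0.53. On the human probe only COL6A1 in chimpanzee, OAT in orangutan and OAT and CD4 in rhesus lay below that median. On the own-species probe only PTPRC and rhesus HPR and FBLN5 lay above it. The other changes of sign went with the offset. With the mean of 4 probes, PTPRC was at 0.0082 in chimpanzee and 0.040 in orangutan and CD4 at -0.050 in rhesus. On probes of the species not compared, PTPRC was at 0.045 and COL6A1 at -0.038 in chimpanzee, CRIM1 at -0.49, KYNU at -0.028 and PTPRC at 0.34 in orangutan, and MAOA at -0.058 and CD4 at -0.11 in rhesus.

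In chimpanzee, COL6A1 was at -0.12 without centring, -0.063 with array weights and -0.047 without the array of conflicting labels. PTPRC was at 0.032 with scaling, 0.074 with array weights and 0.037 on arrays with many failed ratios, and CD36 at 0.0037 and 0.022 in the last 2 settings. Rhesus CD4 was at -0.0031 with array weights. Leaving out each array in turn gave 361 to 424 sets in chimpanzee, 557 to 696 in orangutan, 535 to 697 in rhesus, 394 to 517, 407 to 496 and 473 to 588 in the contrasts and 112 to 240 for the dyes, and 0 to 1 list calls. The probe effect was then 0.37 to 0.50 in chimpanzee, 0.66 to 0.75 in orangutan and 0.99 to 1.04 in rhesus. Without 1 array, COL6A1 ranged from -0.047 to 0.14, PTPRC from -0.078 to 0.056 and CD36 from -0.25 to 0.017 in chimpanzee, and CD4 from -0.020 to 0.023 in rhesus. Further calls lost without 1 array were CETP (0.27 to 0.31), CSF1R (0.22 to 0.30) and FGG (0.28) in chimpanzee, LYN (0.14 to 0.24), KYNU (0.17) and PTPRC (-0.19) in orangutan and APOA1 (-0.32 to -0.27) and C1R (-0.31) in rhesus. The median of duplicate spots and the intensity trend were not run.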

Other observations

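Several genes were lower than in human RNA in all 3 species on the mean of the 4 probes, by limma. RGN was at -1.54 ± 0.10 in chimpanzee, -1.55 ± 0.10 in orangutan and -1.69 ± 0.10 in rhesus. HAO1, which oxidizes glycolate, was at -1.04 ± 0.09, -1.30 ± 0.09 and -1.71 ± 0.09, and AGPAT2 at -1.06 ± 0.15, -1.0003 ± 0.15 and -1.23 ± 0.15. FABP1 was at -2.13 ± 0.13, -0.95 ± 0.13 and -3.09 ± 0.13. Set 43, without a single gene name, was higher in all 3, at 1.78 ± 0.09, 1.03 ± 0.09 and 2.07 ± 0.09. These were chosen after their values were seen.

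Other gene lists fixed before the data were examined had calls in both directions over the 3 species, and none passed the camera test. Within a species, some had calls in 1 direction only. Of 36 transcription factor sets, 4 were higher and 7 lower in chimpanzee, 15 and 8 in orangutan and 12 and 5 in rhesus. Of 30 proteasome and ubiquitin genes, 8 and 5, 8 and 8, and 8 and 6 were higher and lower in the same order of species. Of 15 translation genes the counts were 4 and 2, 4 and 7, and 6 and 2, and of 10 coagulation genes 3 and 3, 5 and 4, and 4 and 2. Of 6 apoptosis genes, 1 was higher and 0 lower in chimpanzee, 4 and 1 in orangutan and 5 and 1 in rhesus. Of 11 genes of oxidative phosphorylation and the citrate cycle, 4 were higher and 1 lower in chimpanzee, 0 and 4 in orangutan and 2 and 4 in rhesus. Of 7 endothelial markers, 1 was higher and 2 lower in chimpanzee, 4 and 1 in orangutan and 0 and 3 in rhesus. Of 26 kinases and phosphatases in signalling the counts were 2 and 3, 6 and 10, and 2 and 8, of 12 splicing genes 3 and 1, 4 and 1, and 5 and 4, and of 10 chaperone genes 1 and 3, 2 and 4, and 4 and 3. The chaperone pattern also caught HSPG2, a matrix proteoglycan. Of 8 genes each, cholesterol and bile acid metabolism gave 3 and 3, 1 and 3, and 4 and 3, cell cycle and DNA replication 0 and 2, 2 and 3, and 2 and 4, and cytoskeleton and adhesion 1 and 2, 4 and 4, and 1 and 3. Of 6 genes of glycolysis and gluconeogenesis the counts were 0 and 2, 0 and 4, and 3 and 1. Where counts adjusted over the list alone differed, they were 7 and 3 for coagulation, 9 and 5 for proteasome, 4 and 3 for translation, 0 and 1 for cell cycle and 2 and 1 for kinases in chimpanzee. In orangutan they were 4 and 2 for apoptosis and 7 and 10 for kinases. In rhesus they were 11 and 4 for transcription factors, 7 and 6 for proteasome, 5 and 2 for translation, 5 and 5 for splicing and 0 and 3 for cytoskeleton.

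Sets lower in all 3 species numbered 78, against 19.9 for independent lists, and sets higher in all 3 numbered 45 against 21.6. Poor binding of non-human RNA to the human probe was a candidate explanation of the excess, and this test was set before its result was seen. On the probes of species that were not compared, the all-lower sets were still 4.37 times the number for independent lists, 68 against 15.6. The ratio on those probes exceeded that on the human probe by a mean of only 0.17 to 0.28. On the own-species probes the excess was 0.43, 0.68 and 1.01. Poor binding may therefore persist on the probes of this test, so it cannot decide the question. Human RNA was in every comparison and may have been the same RNA, which was not tested, so part of the excess may come from it. Changes from human correlated across sets at 0.42 between orangutan and chimpanzee (covariance 0.0881). The correlation was 0.25 between rhesus and chimpanzee (0.0582) and 0.29 between rhesus and orangutan (0.0770). Arrays were also simulated without species differences, with 1 value per pair of species from 20 runs. The correlations were 0.0022 to 0.0033 and the covariances 1.84e-05 to 2.57e-05. The spread between those runs is not given here. The simulated values and the independent lists both leave out a deviation of the human RNA itself, so an excess over them is no evidence of changes shared between the species. Orangutan and chimpanzee shared 89 higher and 128 lower sets against 71.7 and 65.8 for independent lists, rhesus and chimpanzee 98 and 113 against 66.5 and 65.4, and rhesus and orangutan 135 and 165 against 103 and 97.2. These correlations are across genes, and probe sets are not independent replicates.

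The orangutan call for amino acid metabolism was made under 1 of 8 sign patterns of the orangutan arrays, the real one, with 0 list calls under each of the others. These are too few patterns for a share under 0.05.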
